A study of Mus musculus with 2 samples.

How the data were processed

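ATAC-seq had been done on wild-type mouse BMDMs grown with 20 ng/ml M-CSF, in 1 untreated library and 1 library from cells given R848 at 100 ng/ml for 2 h. Per the labels' protocols, cells were lysed, tagmented with a commercial Tn5 kit and amplified for 15 PCR cycles. Reads were processed with bcl2fastq 2.19, aligned with Bowtie2 2.2.6 and called with MACS2 2.2.7.1 on the mm10 build, per the submitters' processing notes, where the tools are listed without their settings. The filters on reads, the handling of duplicates and mitochondrial reads, any shift of insertion sites and the read totals were not given in the sources used here. The authors gave a separate list for each library, and pooling is not mentioned in the labels.

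Each deposited list gives a peak's position, its summit and 4 values. The fold is the pileup at the summit over the background of the same library, as the authors' peak caller wrote it. The deposited −log10 p and −log10 q values are those of the summit within its library. The lowest −log10 p was just above that of a p of 0.01 in both lists, and no q filter was seen. The deposited score was 10 times the −log10 p as a whole number in 99.9% of untreated and 99.8% of R848 peaks, and it was not used further. No list held chromosomes other than 1 to 19, X and Y, and none had repeated positions.

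Depth was approached from the values themselves. The fold is (pileup + 1)/(background + 1) and p is a Poisson tail, so the pileup and background of a peak can be solved together. A solution within 0.1% of the given −log10 p was found for 99.9% of peaks in each list. The genome-wide background so recovered was 0.968 tags in the untreated and 1.36 tags in the R848 library, a ratio of 1.40, which reads as relative depth only if both libraries were extended by the same length. A median pileup of 7 to 8 tags gives low precision for single peaks. Intervals on shares are 95% Wilson intervals over peaks and cover counting error only.

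Peaks were compared by overlap of at least 1 bp with bedtools 2.31.1, and the rest was computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Chance overlap and chance position came from 100 random placements of each list within its chromosomes. Genes were the 21887 protein-coding genes of the RefSeq table of the same build, which gives gene starts and ends without strand or exons. The planned promoter share and the assignment to the nearest transcription start were therefore replaced by the share within 1 kb of either gene end and by the nearest gene end within 100 kb of the summit. The planned shares of 15 sequence motifs needed the genome sequence and were not run. Of the R848-only peaks, 6664 had no gene within reach.

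Gene lists, the rule for naming genes, the measures per list, the bounds and the main alternatives were fixed before the data were examined. The 20 lists covered the primary Toll-like receptor response, NF-kB pathway and feedback, inflammatory cytokines, chemokines, interferon response, Toll-like receptor signalling, JAK-STAT and SOCS, antigen presentation and co-stimulation, macrophage identity, alternative activation, glycolysis and HIF1 targets, cholesterol synthesis, cell cycle, housekeeping, and markers of T and NK cells, B cells, neutrophils, dendritic cells, erythroid cells and megakaryocytes, and stromal and endothelial cells. Cxcl11, Mx1 and Mx2 are not protein-coding in the table and dropped out of their lists, and Emr4 is another name of Adgre4. Some genes are in more than 1 list, at most 3 for any pair. For each list the R848-only peaks per gene and the share of untreated peaks that an R848 peak overlapped were given as percentiles among 10000 random lists of the same size, matched on the number of untreated peaks (0, 1, 2, 3 to 4, 5 to 8, 9 to 16, over 16). A list stood apart at or above 98 or at or below 2. No p-value was computed, since genes are not replicates.

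A further measure per list was added after the data were examined. The share of a list's R848 peaks present in both lists was set against 10000 draws of R848 peaks from the same of 20 strength classes and the same side of the 1 kb gene-end limit. It was calculated for all 20 lists, with peaks drawn singly and without regard to their clustering at genes. Of 1000 random lists of 30 protein-coding genes, 14 stood at or above 98 and 21 at or below 2 in R848-only peaks per gene, and 20 and 30 did in this measure. When drawn only from genes with a peak, 47 of 1000 lists stood at or above 98 and 7 at or below 2 in R848-only peaks per gene, so high percentiles arose more often than the bound implies, and 10 and 32 did in this measure. Smaller runs of 200 lists of genes with a peak came first, and drawing from all protein-coding genes, as for the matched lists, was chosen after they were seen.

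Genes were named by rule: the 12 with the most R848-only peaks, the 12 with the strongest R848-only peaks, the 12 with the most untreated-only peaks with a fold of at least 4.06, which marks the strongest part of the untreated list, up to 4 members per list with the most R848-only peaks and up to 2 with the most untreated-only peaks, and 18 genes chosen in advance such as Tnf, Il1b, Il6 and Nfkbia. Not all genes that met the rule are described, and the selection among them was made after their values were seen.

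The steps were tested on simulated data. All pileups of 20000 simulated peaks were recovered, as were all 3000 planted overlaps. The pileups were simulated with the formulas that the recovery solves, and the planted peaks were untreated peaks shifted by less than their width. Both outcomes therefore check the code and not its match to the deposited lists. Lists of 30 genes with 1 extra R848-only peak per gene were found in 94% of 50 simulations. Alternatives were a stricter threshold (−log10 q of at least 5), lists of equal length, an overlap of 50% of the shorter peak, a gap of up to 500 bp, a gene-end window of 2 kb, gene ends within 20 kb and every gene within 50 kb. The stricter threshold cut both lists before their overlap. A peak that is R848-only there may therefore overlap a weaker untreated peak of the full list. Added after the data were examined were autosomes alone, assignment to the gene that holds the summit, and matching on distance to the gene end as well.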

Results

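Chromatin accessibility was profiled by ATAC-seq in mouse bone marrow-derived macrophages (BMDMs), which are grown out of bone marrow with the growth factor M-CSF. In ATAC-seq the Tn5 transposase inserts sequencing adapters into open DNA, and sites with many insertions are called as peaks. The untreated group held 1 library of wild-type cells. The R848 group held 1 library of wild-type cells given R848 (resiquimod), a small molecule that activates Toll-like receptor 7, at 100 ng/ml for 2 h. There were no replicates, so a peak found in 1 list and not in the other is described here as such and is not a tested change.

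Peaks had been called in each library separately on the mm10 assembly. The untreated list held 77060 peaks covering 24.0 Mb, with a median width of 255 bp. The R848 list held 37725 peaks covering 12.5 Mb, with a median width of 270 bp. Read totals were not given in the sources used here. The genome-wide background recovered from the fold and p columns was 0.968 tags in the untreated library and 1.36 tags in the R848 library. At that background the smallest pileup called as a peak was 4 tags in the untreated list and 5 tags in the R848 list. The median peak held 7 and 8 tags, and 36.5% of untreated and 48.2% of R848 peaks had a q above 0.05, so a single weak peak carries little weight. The fold enrichment given for a peak is the authors' own value and ranks peaks within its list.

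The comparison of stimulated with untreated cells asked where accessible sites differed 2 h after R848. The R848 list held peaks with no untreated counterpart (R848-only peaks) at many genes of the inflammatory response. Il1b, which encodes a pro-inflammatory cytokine released after inflammasome activation, had 6 R848 peaks and no untreated peak assigned to it. Zc3h12a, which encodes a ribonuclease that degrades cytokine mRNAs, had 10 R848-only peaks, and Nfkbia, which encodes the inhibitor that holds NF-kB in the cytoplasm, had 4. Cxcl10, a chemokine that attracts T cells, had 4 R848 peaks and Rsad2, which encodes the antiviral protein viperin, had 3, and neither had an untreated peak. With gene ends within 20 kb the counts of R848-only peaks were 5 for Il1b, 2 for Nfkbia and 2 for Cxcl10, and at a −log10 q of at least 5 they were 2, 0 and 0. Cxcl10 also had 0 when a peak went to the gene that holds its summit.

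The strongest Il1b peak lay on chromosome 2 from 129338175 to 129338584, 26165 bp from the nearer end of the gene, with a fold enrichment of 7.63 and a pileup of 17 tags. At Il12b, which encodes a cytokine subunit that directs T helper cell responses, 3 R848 peaks and 8 untreated peaks were assigned and none of them overlapped. The strongest of these R848 peaks spanned 44390065 to 44390526 on chromosome 11, 9820 bp from the gene, with a fold of 7.87 and 19 tags, while the untreated peaks of Il12b held 5 to 9 tags. At Cxcl2, a neutrophil-attracting chemokine, the strongest R848-only peak lay 128 bp from a gene end on chromosome 5 (90903350 to 90904141), with a fold of 7.32 and 28 tags. At Il10, which encodes an anti-inflammatory cytokine, the R848-only peak lay on chromosome 1 from 131038027 to 131038384, 13243 bp from the gene, with a fold of 7.21. The gene table used here gave the ends of each gene and no exons, so a peak inside a gene could not be placed in an exon or an intron.

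**Figure D1:**
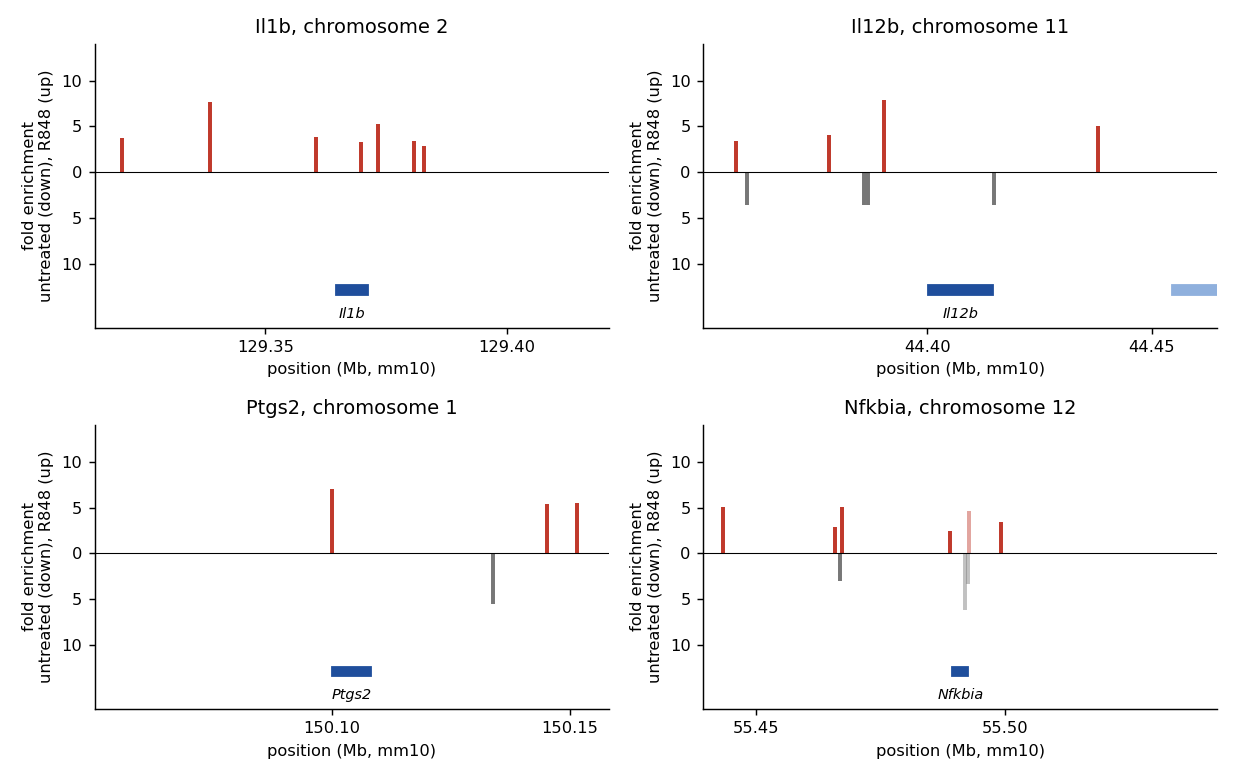
Peaks around Il1b, Il12b, Ptgs2 and Nfkbia, within 50 kb of each gene, with the position on mm10 in Mb on the x axis and the fold enrichment of each peak on the y axis (R848 peaks upward in red, untreated peaks downward in grey, paler where the peak overlaps one in the other list; blue bars are protein-coding genes, and a peak drawn may be assigned to a neighbouring gene). No untreated peak is drawn near Il1b, and the tallest bars at Il1b and Il12b are R848-only peaks with folds of 7.63 and 7.87.

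R848-only peaks also lay at 2 neighbouring chromosome 1 genes of prostaglandin synthesis. Pla2g4a, which encodes the cytosolic phospholipase that releases arachidonic acid, had 14 R848 peaks, the largest number of R848-only peaks when a peak went to the nearest gene end within 100 kb, and 6 untreated peaks that overlapped none of them. When a peak went to the gene that holds its summit, Wwox had more, with 17, and with lists of equal length Gm15319 had more, with 15. Ptgs2, the inducible cyclooxygenase, had 4 R848-only and 5 untreated-only peaks, and its R848-only count was 1 with gene ends within 20 kb. One of the Ptgs2 peaks lay 46 bp from a gene end (150099587 to 150100312) with a fold of 7.03 and 17 tags. The strongest peak assigned to Ptgs2, 56838 bp from the gene, had a fold of 10.7 in the R848 list and was present in both lists.

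Other genes with many R848-only peaks were Gli2, a transcription factor of hedgehog signalling, with 13, Klf6, a zinc finger transcription factor, with 11, Ptpre, a protein tyrosine phosphatase, with 11, Xxylt1 with 11, Peli2, a ubiquitin ligase of Toll-like receptor signalling, with 10, and Wwox with 10. Untreated-only peaks numbered 6 at Gli2, 5 at Klf6, 1 at Ptpre, 6 at Xxylt1, 5 at Peli2 and 11 at Wwox. The strongest of these had folds, within the untreated list, of 9.91 at Wwox, 7.21 at Xxylt1 and 6.60 at Klf6. With gene ends within 20 kb the R848-only counts were lower, at 9 for Pla2g4a, 2 for Gli2, 3 for Klf6, 4 for Ptpre, 6 for Xxylt1, 2 for Peli2 and 0 for Wwox. At a −log10 q of at least 5 they were 3 for Pla2g4a, 0 for Gli2, 2 each for Klf6, Ptpre and Wwox, and 1 each for Xxylt1 and Peli2. With every gene within 50 kb they were 14 for Pla2g4a, 6 for Gli2, 5 for Klf6, 10 for Ptpre, 8 for Xxylt1, 7 for Peli2 and 6 for Wwox. The Peli2 gene held an R848-only peak with a fold of 9.06 and 24 tags (chromosome 14, 48131339 to 48131968). A530032D15Rik, Zfp600, Gm10573, Gm21119 and Gm15319 also ranked among the 12 genes with the most R848-only peaks, and these are uncertain because each belongs to a family of near-identical copies.

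Ranked by fold within the R848 list, the strongest R848-only peaks were assigned to Etv1 (11.2), Plekhg1 (10.9), Gpr65 (10.7), Ndufaf5 (10.7), Sec14l2 (10.5), Tasp1 (10.3), Tmem260 (10.3), Adora2a (10.1) and Virma (10.1), with Rsu1, Josd2 and Osbpl10 next. Gpr65 encodes a proton-sensing receptor and Adora2a an adenosine receptor that restrains inflammation. The Adora2a peak lay inside the gene on chromosome 10 (75326598 to 75327080) and held 42 tags. The Etv1 peak lay 34265 bp outside the gene on chromosome 12 (38904525 to 38905009) and held 30 tags. The Ndufaf5 and Josd2 peaks lay 4 and 28 bp from a gene end.

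Several other well-known genes had 0 to 3 R848-only peaks when each peak went to its nearest gene end, against a mean of 0.885 over all protein-coding genes. Tnf, which encodes a pro-inflammatory cytokine, had 1 R848-only peak, 121 bp from a gene end with a fold of 4.63, and 1 peak in both lists. Il6 had 5 untreated peaks of 5 to 7 tags and no R848 peak. Ifnb1, which encodes a type I interferon, had 2 R848-only and 4 untreated-only peaks, and Nos2, the inducible nitric oxide synthase, had 3 and 2. Irf1, an interferon-induced transcription factor, had 1 R848-only peak 61 bp from a gene end with a fold of 6.12 and 2 untreated-only peaks, the stronger with a fold of 7.11. Tnfaip3, a deubiquitinase that limits NF-kB signalling, had 3 R848-only peaks, 4 untreated-only peaks and 4 R848 peaks present in both lists. Socs3, a feedback inhibitor of cytokine signalling, had 3 R848-only peaks, 1 untreated-only peak and 2 R848 peaks present in both lists. No peak was assigned to Ccl5 or Tlr7, the gene of the R848 receptor, in either list. Tlr7 lies on X, where the R848 list held few peaks. When a peak counted for every gene within 50 kb, R848-only peaks numbered 7 for Tnf, 2 for Il6 and 3 for Ccl5, with 0 for Tlr7. Actb, the cytoskeletal beta actin, had 4 peaks in each list, of which 3 in each were shared. Csf1r, the M-CSF receptor, had 2 R848-only peaks.

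Gene groups were compared by the number of R848-only peaks per gene, given as a percentile among 10000 random lists with matched numbers of untreated peaks. Of 20 lists fixed in advance, 9 stood at or above the percentile of 98. Over all protein-coding genes, 10339 of 21887 had an R848-only peak, so the number of members with such a peak says less than the percentile. Genes of the primary Toll-like receptor response had 2.34 R848-only peaks per gene against a mean of 1.09 in random lists (percentile 100), with such a peak at 31 of 35 members, including Klf6 with 11 and Atf3 and Ier5 with 5 each. NF-kB pathway and feedback genes had 2.21 per gene against 1.00 (percentile 100), at 19 of 28 members, among them Zc3h12a with 10, N4bp1 with 5 and Nfkbia with 4. Inflammatory cytokines and mediators had 2.09 against 0.884 (percentile 100), at 26 of 34 members. These included Inhba, an activin subunit, with 8 beside 11 untreated-only peaks, Il1b and the vasoconstrictor gene Edn1 with 6 each, and Acod1, the itaconate-producing enzyme, with 4. Chemokines had 1.48 against 0.677 (percentile 99.9), at 15 of 21 members, with 4 each at Ccl9 and Cxcl10 and 3 each at Cxcl2 and Ccl2. Bcl2a1d, with 5, has near-identical paralogs and is uncertain.

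The other 5 of these lists covered cell identity, surface molecules and signalling. Macrophage identity genes had 2.21 R848-only peaks per gene against 1.24 (percentile 100), at 30 of 38 members, with 10 at the scavenger receptor gene Msr1, which had 10 untreated-only peaks as well, 8 at the transcription factor gene Cebpb and 5 at Spi1, which encodes the lineage factor PU.1. JAK-STAT and SOCS genes had 1.75 against 1.04 (percentile 99.2), at 21 of 24 members, with 6 at Il4ra and 5 at Il10rb, both cytokine receptor genes. Genes of antigen presentation and co-stimulation had 1.60 against 0.759 (percentile 99.9), at 19 of 25 members, with 4 at Cd86, Cd44, Cd69 and Pdcd1lg2. Dendritic cell markers had 1.71 against 0.821 (percentile 99.7), at 10 of 17 members, with 7 at Tcf4 and 5 at Kit. Without Tcf4, the percentile of the dendritic cell list was 97.7. Toll-like receptor signalling genes had 1.33 against 0.829 (percentile 98.7), at 22 of 33 members, with 5 at the kinase gene Irak2 and 3 at Ikbkb, which had no untreated peak.

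The same 9 lists held untreated-only peaks as well. Over the whole genome there were 65279 untreated-only and 26035 R848-only peaks, a ratio of 2.51, which includes peaks with no gene within reach. In each of the 20 lists, whose counts hold assigned peaks alone, the ratio was lower, so this does not set the 9 lists apart. A gene with more untreated-only than R848-only peaks is thus not unusual. R848-only and untreated-only peaks numbered 82 and 53 for the primary Toll-like receptor response, 62 and 42 for NF-kB genes, 71 and 66 for inflammatory cytokines, and 31 and 16 for chemokines. They numbered 84 and 112 for macrophage identity, 42 and 36 for JAK-STAT and SOCS, 40 and 23 for antigen presentation, 29 and 26 for dendritic cell markers, and 44 and 46 for Toll-like receptor signalling. Several members had more untreated-only than R848-only peaks. These included Il15, a cytokine gene of lymphocyte survival, with 11 untreated-only and 3 R848-only peaks, the scavenger receptor gene Cd36 with 10 and 3, and Nr4a2, a nuclear receptor gene, with 7 and 0. Ly96, which encodes the Toll-like receptor 4 partner MD-2, had 7 and 2, Stat4 had 6 and 2, Map3k7 had 6 and 3, Nfkb1 had 5 and 3, and the chemokine gene Ccl8 had 5 and 1. In the lists between the bounds, Cd163, a haemoglobin scavenger receptor gene, had 6 and 0, and the interferon response genes Ifi44 and Gbp2 had 7 and 2, and 5 and 1.

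The remaining 11 lists lay between the percentiles of 2 and 98. Interferon response genes had 0.896 R848-only peaks per gene (percentile 78.0), at 29 of 48 members, with 3 each at Rsad2, Gbp5 and Ddx58. Alternative activation and homeostatic genes had 1.45 (97.7), glycolysis and HIF1 target genes 1.35 (95.7) and cholesterol synthesis genes 1.30 (93.9). Of these, the cholesterol exporter gene Abca1 had 8, Pfkp, a glycolytic phosphofructokinase gene, had 6, and the lanosterol synthase gene Lss had 4. Housekeeping genes had 0.885 (82.7) and cell cycle genes 0.964 (86.4). Markers of other cells gave 0.941 for neutrophils (89.4), 1.40 for stromal and endothelial cells (82.6), 0.588 for B cells (39.9), 0.696 for T and NK cells (33.7) and 0.50 for erythroid cells and megakaryocytes (18.8). An R848-only peak lay at 17 of 26 housekeeping genes, 15 of 20 stromal and endothelial markers and 11 of 17 neutrophil markers. Such a peak lay at 7 of 23 T and NK cell markers, 7 of 17 B cell markers and 7 of 18 erythroid and megakaryocyte markers. When both lists were reduced to a −log10 q of at least 5, the percentile was 75.8 for chemokines, 88.7 for antigen presentation, 73.5 for dendritic cell markers and 97.4 for Toll-like receptor signalling, while housekeeping genes (99.9), glycolysis (99.7) and cholesterol synthesis (99.6) rose above 98. When a peak counted for every gene within 50 kb, interferon response genes (99.4) and neutrophil markers (99.7) rose above 98 and Toll-like receptor signalling stood at 96.1. Alternative activation genes rose above 98 with lists of equal length (99.5), where Toll-like receptor signalling stood at 95.4, and with gene ends within 20 kb (98.7), where cholesterol synthesis passed 98 as well. Of 1000 random lists of genes with a peak, 47 stood at or above 98, and of 1000 lists drawn from all protein-coding genes 14 did. These percentiles describe 1 pair of libraries.

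The share of a list's untreated peaks that an R848 peak overlapped was the other planned measure. Housekeeping genes kept 63.6% of 33 untreated peaks against 30.2% in random lists (percentile 100). The share was also high for genes of the primary Toll-like receptor response (49.5%), cell cycle (48.7%), cholesterol synthesis (46.3%), JAK-STAT and SOCS (45.5%), NF-kB (41.7%), glycolysis (41.5%) and macrophage identity (28.2%). Stromal and endothelial markers kept 5.08% of 59 peaks against 17.9% in random lists (percentile 0.285), the single list at the low end. That percentile was 5.16 with a gap of up to 500 bp and 9.04 at a −log10 q of at least 5, and it was 7.85 against untreated peaks of the same strength. Against peaks of the same strength, cell cycle (97.4) and cholesterol synthesis (95.7) also left the high lists, while Toll-like receptor signalling (98.2) and antigen presentation (99.3) joined them. With both lists reduced to a −log10 q of at least 5, 1 of the 8 high lists stayed at or above 98, and the macrophage identity genes stood at percentile 7.30. Lists of equal length brought 2 of 20 lists back between the bounds in this measure, and gene ends within 20 kb also brought back 2. The other 11 lists kept between 10.5% of the untreated peaks, for B cell markers, and 43.8%, for neutrophil markers, and stood between the bounds.

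Because strong peaks were shared more often than weak ones, each list's R848 peaks were also compared with R848 peaks of the same strength and the same nearness to gene ends, a comparison added after the lists were seen. Near inflammatory cytokine genes, 14.5% of 83 R848 peaks overlapped an untreated peak, against 32.4% of matched peaks (percentile 0.005). Near chemokine genes the share was 16.2% of 37 peaks against 32.6% (percentile 0.665), and near interferon response genes 21.8% of 55 peaks against 37.3% (percentile 0.25). The other 17 lists lay between the bounds, with NF-kB genes at percentile 5.46, housekeeping genes at 27.7 and macrophage identity genes at 78.6. With a −log10 q of at least 5 the percentiles were 8.55 for cytokines (17 peaks), 32.9 for chemokines (6 peaks) and 13.9 for interferon response genes (13 peaks), while NF-kB genes stood at 1.02 (26 peaks). With lists of equal length, chemokines stood at 3.76, while stromal and endothelial markers (0.425, 31 peaks) and cholesterol synthesis genes (1.76, 43 peaks) fell below 2.

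**Figure D2:**
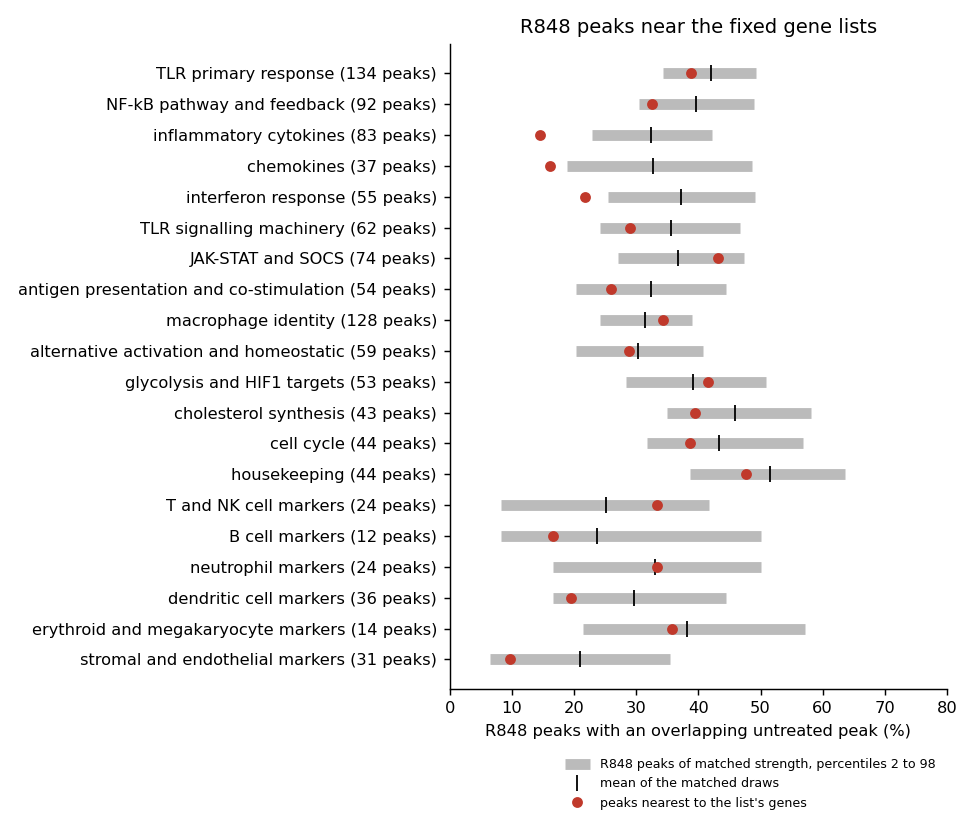
Share of R848 peaks with an overlapping untreated peak (x axis, %) for the peaks nearest to the genes of each of 20 fixed lists (red points), with the mean (black ticks) and the percentiles 2 to 98 (grey bars) of 10000 draws of R848 peaks matched on strength and nearness to gene ends. The points for inflammatory cytokines (14.5%), chemokines (16.2%) and the interferon response (21.8%) lie left of their bars.

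Across the genome, 11690 R848 peaks (31.0%, 95% Wilson interval 30.5 to 31.5) overlapped an untreated peak, and 26035 were R848-only. In the other direction 11781 untreated peaks (15.3%, interval 15.0 to 15.5) overlapped an R848 peak, and 65279 were untreated-only. Placing the peaks at random gave overlaps of 1.82% and 0.896%. The share overlapping grew with strength, from 15.2% in the weakest of 10 equal strength groups of the R848 list to 88.2% in the strongest, and from 4.61% to 51.8% in the untreated list. With both lists cut to a −log10 q of at least 5 the order of the list lengths turned, with 4720 untreated and 6267 R848 peaks. Of these, 2522 and 4076 had no counterpart in the other cut list, though they may overlap a weaker peak of the full list. With lists of equal length, 28851 untreated and 28849 R848 peaks had none.

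**Figure D3:**
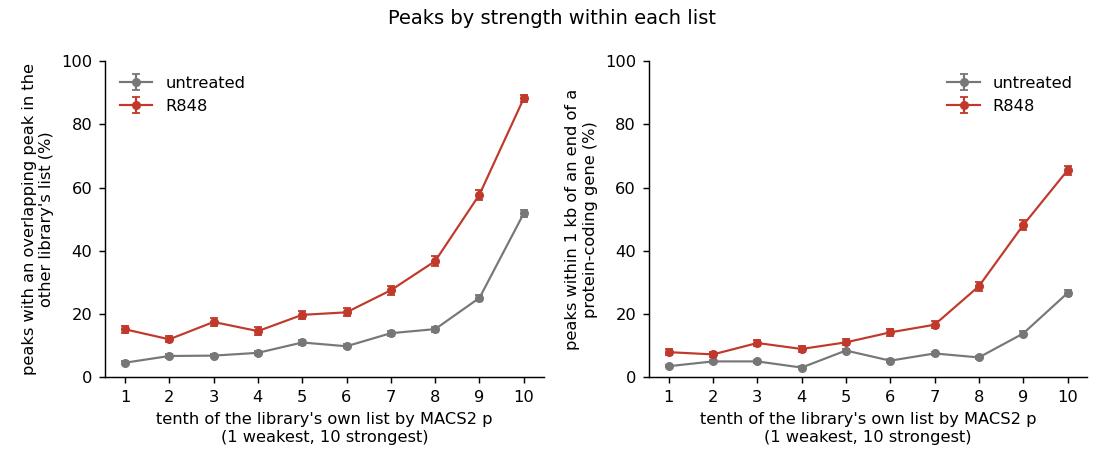
Share of peaks with an overlapping peak in the other list (left, %) and share of peaks within 1 kb of an end of a protein-coding gene (right, %), in 10 equal groups of each library's own list ordered by MACS2 p, with 95% Wilson intervals. Both shares are highest in the strongest group, where 88.2% of R848 and 51.8% of untreated peaks were in both lists.

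Peaks within 1 kb of an end of a protein-coding gene numbered 8271 in the R848 list and 6523 in the untreated list. Among peaks in both lists, 41.0% of R848 peaks lay at a gene end. Among R848-only peaks the share was 13.4% (95% interval 13.0 to 13.8) against 3.51% for shuffled peaks, and among untreated-only peaks it was 2.60% (2.48 to 2.73) against 3.29%. Of the 2603 R848-only peaks with the highest fold 34.3% lay at gene ends, and of the 6527 untreated-only peaks with the highest fold 2.36% did, each being the top 10% of its set. R848-only peaks were assigned to 10339 of 21887 protein-coding genes, and 2253 genes had an R848-only peak and no untreated peak. With both lists cut to a −log10 q of at least 5, 3495 genes had an R848-only peak and 58.0% of these peaks lay at gene ends. Some of these peaks may overlap a weaker untreated peak that the cut left out.

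Strong untreated-only peaks, those with a fold of at least 4.06, were most numerous at 12 genes outside the macrophage and inflammatory lists. The counts were not scaled to the stretch of genome assigned to each gene. Several of these genes are long, such as Sox5 (chromosome 6, 143828425 to 144782287), though Slc30a8 (chromosome 15, 52295553 to 52335798) is not. The ranking therefore says little about what the genes do. Cntn3, a neuronal cell adhesion gene, had 9, followed by the transcription factor gene Sox5, Cep128, Egfem1 and the glutamate receptor gene Gria1 with 8 each. Kiz, the pancreatic zinc transporter gene Slc30a8, Reps2 and Slc35f1 had 7 each, and Sulf1, Pak3 and the calcium channel subunit gene Cacna2d1 had 6 each. R848-only peaks at these 12 genes numbered 7 at Sox5, 3 each at Cep128, Egfem1, Sulf1 and Cacna2d1, 1 each at Cntn3, Gria1, Slc30a8 and Reps2, and 0 at Kiz, Slc35f1 and Pak3. Reps2 and Pak3 lie on X, where the R848 list held few peaks. The strongest such peak of these genes was assigned to Sulf1, which encodes an extracellular sulfatase. That peak lay outside the gene on chromosome 1 (12644611 to 12644991), with a fold of 24.1 and 70 tags.

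Peak density followed gene density differently in the 2 sets. R848-only peaks numbered 6.11 per Mb (SD 3.64, 328 windows) in autosomal windows of 1 Mb without protein-coding genes and 15.1 per Mb (SD 6.50, 250 windows) in windows with over 20 genes. Untreated-only peaks numbered 24.5 (SD 12.2) and 20.9 (SD 8.57) per Mb. R848 peaks in both lists numbered 1.86 (SD 1.73) and 9.49 (SD 5.32) per Mb.

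**Figure D4:**
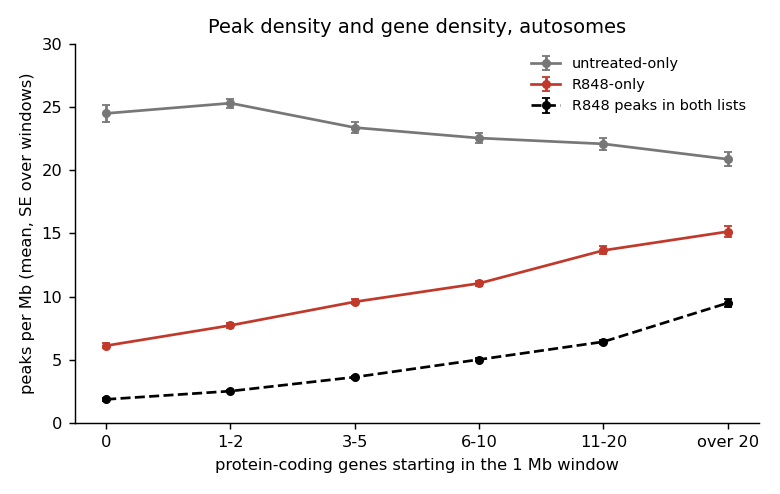
Mean number of peaks per Mb (y axis, bars give the standard error over windows) in autosomal windows of 1 Mb grouped by the number of protein-coding genes that start in them (x axis), for untreated-only peaks (grey), R848-only peaks (red) and R848 peaks in both lists (black, dashed). The red line goes from 6.11 to 15.1 peaks per Mb and the grey line from 24.5 to 20.9.

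The lists also differed on the sex chromosomes. The untreated list held 4556 peaks on X and 3763 on Y, and the R848 list held 820 and 184. Relative to autosomal windows of like gene density, the untreated list had 0.965 times as many peaks per Mb on X and 1.51 times as many on Y, and the R848 list 0.351 and 0.171 times. Peaks in both lists were at 0.582 of the autosomal density on X in the untreated list and at 0.591 in the R848 list. Without X and Y, 57433 untreated-only and 25507 R848-only peaks remained.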

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

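The tests on the untreated list in this part were chosen after the result was seen, and the test on gene density was narrowed to peaks away from gene ends, because peaks in both lists reach a ratio of only 1.79 there. The limit of this test, a ratio under 1, was set after its value was known. Over all untreated-only peaks that ratio was 0.852. The background recovered from the fold and p columns, values outside the peak comparison itself, was 1.40 times as high in the R848 library as in the untreated library.

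The untreated list was 2.04 times as long as the R848 list. Deeper sequencing of the untreated library would need a lower background in the R848 library, and the ratio of 1.40 goes against it if reads were extended alike. Untreated-only peaks lay at gene ends 0.792 times as often as shuffled peaks, so calls scattered over the genome may make up much of the longer list. This low share is partly built in, since 4823 of the 6523 untreated peaks at gene ends were in both lists. Over the whole untreated list the share was 8.46% against 3.35% for shuffled peaks. Closed sites away from gene ends would give a low share too, so this value does not tell them from scattered calls. Sites that lost accessibility after R848, as the bulk of the untreated-only peaks, would be expected to follow gene density away from gene ends as peaks in both lists do (1.79), and the ratio of gene-rich to gene-free windows was 0.760. This assumes that closing sites are placed like the shared ones. Whether any single site closed, such as that of the untreated-only peak assigned to Sulf1, was not tested and stays open.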

How the results depend on the processing

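The alternatives fixed in advance covered peak sets, gene ends and both planned list measures, and the settings for autosomes, for the gene that holds the summit and for matching on distance were chosen after the data were seen, as was the measure at matched strength. No paired analysis was possible because each group had 1 library. The motif shares were not run, and promoter shares and nearest starts were replaced by gene ends. The causes of the shifts were not tested, apart from those that follow from fewer or longer peaks. Low pileups limit every value.

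The stricter threshold cut both lists before their overlap, so weaker peaks of the full lists did not count as counterparts. It gave 4076 R848-only and 2522 untreated-only peaks, overlap shares of 35.0% and 46.6%, gene-end shares of 58.0% and 5.71%, and 3495 genes. At matched strength none of the 3 low lists stayed low and 1 other, NF-kB genes (1.02), became low. In untreated peaks kept cholesterol synthesis (99.5) stayed high, T and NK cell markers became low (1.83), and the kept percentile turned for JAK-STAT (34.4), glycolysis (39.9) and macrophage identity (7.30). With lists of equal length there were 28851 untreated-only peaks, overlap shares of 23.5% and 23.5%, and gene-end shares of 15.4% and 2.32%. With an overlap of 50% the overlap shares were 28.2% and 13.9%, and the untreated-only gene-end share 2.84%. Within 500 bp these were 35.7%, 18.2% and 2.33%. With a 2 kb window the gene-end shares were 17.2% and 4.25%. Every gene within 50 kb gave 16712 genes and 5 lists high in untreated peaks kept, with Toll-like receptor signalling (98.5) gained and NF-kB (96.5), glycolysis (97.7), cholesterol synthesis (82.9) and macrophage identity (97.7) lost. On autosomes 16.5% of untreated peaks overlapped and 2.73% of untreated-only peaks lay at gene ends.

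Lists high in R848-only peaks per gene numbered 8 to 11 over all settings. The stricter threshold changed 7 of 20 calls in this measure, and TLR signalling genes lost theirs under 3 settings. Of 42 genes, 13 kept their count of R848-only peaks within 1.5 times under the stricter threshold, and 20 with gene ends within 20 kb. Both counts include Ccl5, Il6 and Tlr7, which had 0 R848-only peaks in the main setting and in these settings, and so none to lose.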

Other observations

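The tests on the sex chromosomes and on the gene lists in this part were chosen after the results were seen, as were the 9 lists weighed together and the minimum of 30 peaks per setting. Genes with no untreated peak and at least 3 R848-only peaks numbered 166. Besides Il1b, Cxcl10, Rsad2 and Ikbkb, they include Cx3cr1, the fractalkine receptor gene, with 3, Lss with 4 and the transcription factor gene Gfi1 with 4. The 3 Cx3cr1 peaks had folds of 5.09, 4.86 and 4.74 and held 11 to 13 tags. The strongest Lss peak had a fold of 8.48.

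The R848 list held few peaks on X and Y. R848 cells from a female and untreated cells from a male would leave X near the autosomes in the R848 list, and it stood at 0.351. On X the ratio to autosomes differed 2.75 times between the lists. This is the gap itself, so it does not test a part of reads assigned to the repeats of Y in the untreated library. For Y this explanation cannot be told apart from others, since the lists hold no mapping quality and the first 4 Mb, with most single-copy genes, gave an untreated ratio of 1.19 over 4 windows. Untreated-only peaks had a ratio of 1.03 on X where peaks in both lists had 0.582, and a difference of treatment or preparation stays open.

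The 9 lists with many R848-only peaks may have them because weak sites were missed in the untreated library, or because sites opened after R848. For inflammatory cytokines, sensitivity lowered alike at all R848 peaks of like strength is argued against by the comparison at matched strength. Its percentiles were at most 0.24 in every setting that left 30 or more peaks, though 8.55 with the 17 peaks of the stricter threshold. Interferon response genes, outside the 9 lists with a percentile of 78.0 in R848-only peaks per gene, stood at 0.09 to 1.11 in such settings. They stood at 13.9 with the 13 peaks of the stricter threshold. With lists of equal length stromal markers, which are not tied to the stimulus, reached 0.425. The settings reuse the same peaks, and peaks drawn singly ignore their clustering at genes, so the percentiles may overstate the rarity. A sensitivity lowered more near these genes stays open. For chemokines lower sensitivity stays open, since lists of equal length gave 3.76. It stays open for the other 7 lists too, where the lowest percentile in settings with 30 or more peaks was 1.14, for dendritic cell markers within 500 bp. Of these 7 lists, no other passed a bound in such settings. Macrophage identity genes stood at 60.2 to 87.9 and JAK-STAT genes at 39.6 to 95.7, as lower sensitivity would give, though such values do not single it out. Under the stricter threshold macrophage identity genes stood at 16.6 (17 peaks) and JAK-STAT genes at 2.13 (18 peaks). Another difference between the 2 preparations cannot be told apart from R848 with 1 library each. The housekeeping list stood at 82.7 and at 99.9 under the stricter threshold. Whether such a difference would raise that list is not known, so neither value decides. An opening of sites near cytokine genes by R848 is therefore a hypothesis that replicate libraries would test.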
